A study of Homo sapiens with 4 samples.

How the data were processed

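Total RNA was measured in 4 samples of HHUA cells, a human endometrial adenocarcinoma line: 2 controls and 2 treated with scytonemin for 48 h. Scytonemin is a yellow-brown pigment of cyanobacterial sheaths that screens ultraviolet light and is known to inhibit polo-like kinase 1 (PLK1). Per the labels, both groups grew in DMEM with serum, and the controls had no scytonemin; the dose, and whether the controls were given a vehicle, are not stated. Nothing in the labels says that the replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

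Cy3-labelled cRNA was hybridized to 1-colour Agilent 4x44K arrays with 1 sample per array. Per the file headers, all 4 arrays were on 1 slide and came from 1 scan, in the order control 1, scytonemin 1, control 2, scytonemin 2. The deposited array files hold the intensity of each spot in Agilent Feature Extraction output (9.1.3.1 per the file headers, 9.1 per the labels). The processed signal is an intensity that the authors' software background-subtracted and detrended within each array and did not scale between arrays. The deposited files also hold median spot and local background intensity, and 0 or 1 marks for spots well above background, saturated or outlying. The authors also deposited a table of genes with higher signal and a table of genes with lower signal; their values are ratios, read as the ratio or fold of scytonemin over control because all exceed 1 in the first and fall under 1 in the second. How the authors averaged or normalized those ratios is not stated.

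The processed signal was log2-transformed and scaled by subtracting the log2 of its 75th percentile in each array. Control spots and spots with an outlier mark were left out, and the spots of a probe were averaged. A probe was kept where it was well above background on both arrays of at least 1 group. The files hold no gene names, so probes were named through their RefSeq accession in the RefSeq gene table of the current human assembly; 23434 of 41000 probes received a symbol, and the rest kept their accession. The genome build behind the array's design is not given in the files, so no coordinates are printed. A gene with several kept probes was represented by the probe with the highest mean signal over all 4 arrays. Of 4516 genes with several tested probes, 4 (HM13, LPP, ZBTB41 and ZC3HAV1, named after their values were seen) had probes of opposite sign that were each at an unadjusted p under 0.05. This left 20330 genes, of which 11828 had a symbol and 8502 did not.

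Scytonemin was compared with control by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes, no intensity trend, no replicate block, and a two-sided Benjamini-Hochberg adjusted p threshold of 0.05 over all genes tested. Log2 fold changes are given with the moderated standard error, and each group held 2 arrays. As a description without a test, genes were counted whose log2 difference was at least 1 in each of the 4 pairings of a treated with a control array. A fold for a gene that was on no array of a group well above background is a lower bound, computed against the mean over those arrays of the gene's own signal or, where that is lower, the lowest signal well above background on the array, and is written as at least N-fold.

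Before the data were examined, 34 gene lists, the fits, the alternatives and the rule for named genes were fixed. The lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the 34 lists), which compares a list with all other genes, and again with camera using an estimated correlation and with fry. Members were also adjusted over the list alone. A gene with a lower bound occurred in the immediate early, NRF2 and aryl hydrocarbon receptor lists alone, 1 in each. Holding it at that bound moved 0 of the list medians. The gene stayed above the median of its list each time, so this says nothing of the list tests. The list tests used the values without the bound and were not rerun. The rule for named genes took, among genes with an official symbol, up to 15 per direction past the threshold with the same sign in every pair; where fewer than 10 passed, the 10 largest changes among genes above background on all 4 arrays with the same sign in every pair; up to 4 members per list past the threshold, or the 2 with the largest change; PLK1; and the 5 largest entries of each of the authors' tables.

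The 75th percentile of processed signal was 1620 in control 1, 1382 in scytonemin 1, 1378 in control 2 and 1119.5 in scytonemin 2, and 64.8, 65.4, 65.4 and 62.2 percent of probes were well above background. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.10. The same code was tested on simulated data of 20330 genes with 50 genes changed at each size. It called 1 gene changed 1.5-fold, 24 changed 2-fold, 44 changed 4-fold and 50 changed 8-fold, with 8 of 20130 unchanged genes also called. All sizes were adjusted together, so the 4-fold and 8-fold genes eased the threshold for the smaller changes. These counts therefore do not give the share of 2-fold changes that would be called in the real data. A shifted list was found and 0 unchanged lists were. The simulated genes varied independently of each other, so the simulation cannot tell how often camera calls unchanged lists of correlated genes.

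The alternatives were quantile normalization; normexp background correction with an offset of 50, scaled by the 75th percentile or by quantiles; the percentile over probes above background on all arrays; no filter and a stricter filter on dim probes; outlying spots kept; an intensity trend with a robust prior; the mean of a gene's probes; all probes tested; a replicate block; and each array left out. The mean spot intensity planned for normexp is not in the files, so the median spot and background intensity were used. A slide or scan block could not be run because all arrays share 1 slide and 1 scan. Array position as a covariate and scaling on the spike-in probes were added after seeing the data. Lists of YAP/TEAD targets and of SRF/MRTF targets were also added then.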

Results

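Gene expression was measured on 1-colour arrays in HHUA endometrial cancer cells, with 2 control samples and 2 samples treated with scytonemin for 48 h. Of 20330 genes tested, 19450 were well above background on all 4 arrays, and 0 spots were saturated. Log2 signals of array pairs correlated across genes at 0.990 to 0.997; genes are not independent replicates. The SD of the log2 difference between arrays was 0.24 for the controls and 0.33 for the treated samples. Between scytonemin 1 and controls 1 and 2 it was 0.30 and 0.28, so scytonemin 1 lay closer to the controls than to scytonemin 2. Between scytonemin 2 and controls 1 and 2 it was 0.43 and 0.39. On the first principal component, which held 60.9 percent of the variance, the controls lay at -23.4 and -15.5, scytonemin 1 at 2.97 and scytonemin 2 at 35.9, so scytonemin 2 stood farthest from the controls.

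The comparison of scytonemin with control asks which genes differ in HHUA cells after 48 h with the compound. The early growth response transcription factor EGR1 was 6.68-fold higher in treated cells (log2 fold change 2.74 ± 0.52 SE, n = 2 per group). SESN2, a stress-induced regulator of metabolism, was 2.90-fold higher (1.54 ± 0.31), the pro-apoptotic BMF 2.72-fold (1.44 ± 0.22), and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, 2.54-fold (1.35 ± 0.20). CYP1A1, a xenobiotic-metabolizing enzyme, was 2.64-fold higher (1.40 ± 0.13). Lower signals were measured for ANKRD1, a transcriptional cofactor (log2 fold change -1.74 ± 0.09), the matricellular factor CCN2 (-1.38 ± 0.17), the troponin gene TNNC1 (-1.53 ± 0.12) and endothelin EDN2 (-1.45 ± 0.39). None of these named genes passed the adjusted p threshold of limma: the adjusted p was 0.246 for EGR1, 0.253 for SESN2, 0.204 for BMF and CDKN1A, 0.128 for CYP1A1 and TNNC1, 0.152 for CCN2, 0.310 for EDN2 and 0.0631 for ANKRD1.

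The 10 largest changes per direction were taken among genes with a symbol, above background on all arrays and with the same sign in every pair. Other higher genes among these were the metalloproteinase MMP26 (1.73 ± 0.26), AMBP, the alpha-1-microglobulin precursor (1.46 ± 0.13), the transcription factor TFCP2L1 (1.43 ± 0.16) and the nuclear receptor NR4A1 (1.34 ± 0.22). CABP1 (1.72 ± 0.78) differed by 0.50 to 2.95 between pairs of arrays, with most of its change in scytonemin 2. Among the 10 largest lower genes were ZBED2 (-1.36 ± 0.10) and the pregnancy-specific glycoproteins PSG3 (-1.46 ± 0.34) and PSG4 (-1.39 ± 0.25), a family of near-identical genes whose probes may not tell members apart. GNG13 (-3.07 ± 1.84), GPR142 (-2.21 ± 1.36) and OR6W1P (-1.86 ± 0.82) rested on control 1. GNG13 had a normalized log2 signal of 1.27 in control 1 but -4.35 in control 2, near the -4.76 and -4.45 of the treated arrays. PLK1, the kinase that scytonemin is known to inhibit, had a log2 fold change of -0.25 ± 0.11 (adjusted p = 0.429) and was lower in all 4 pairs. The array measures RNA and cannot show inhibition of the kinase. The fixed list of G2 and M phase genes, which holds PLK1, had a median of -0.20.

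**Figure D1:**
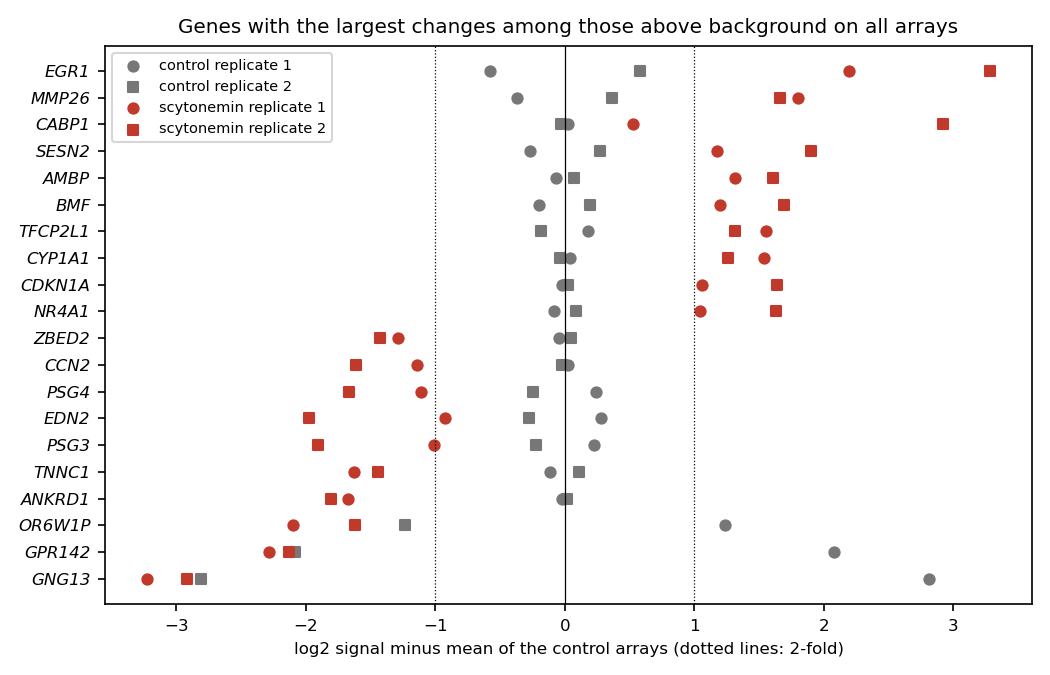
Log2 signal of each array minus the mean of the 2 control arrays (x axis) for the 10 genes with the largest increase and the 10 with the largest decrease. They were taken among genes with a symbol, above background on all arrays and with the same sign in every pair. Grey marks are control replicates, red marks are scytonemin replicates, and dotted lines are 2-fold. By that choice the treated arrays lie on 1 side of both controls for each gene. For GNG13, GPR142 and OR6W1P control 2 lies beside the treated arrays.

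Over all genes, limma called 1 gene at an adjusted p under 0.05, a transcript without a symbol (accession BX379032, probe A_32_P93403; named after its values were seen). It was at least 4.33-fold higher with scytonemin, was on no control array well above background, and was higher in 4 of 4 pairs. The adjusted p of 0.00187 by limma belongs to the log2 fold change without the bound, 4.44 ± 0.08. That value and its error rest on control signals of -8.72 and -8.70. The lowest signals well above background on those arrays were -6.39 and -6.38. The count was 0 with normexp and the 75th percentile, with no filter and with the stricter filter on dim probes. It was 4 with quantile normalization, 9 with normexp and quantiles, 5 with the mean of a gene's probes and 2 with all probes tested. It was 11 with a replicate block, 69 with an intensity trend and robust prior, and 215 with scaling on the spike-in probes. Beside those counts of 0, limma gave 2292, 2013 and 2537 genes at an unadjusted p under 0.05. At an unadjusted p under 0.05, limma gave 2590 genes, 1094 higher and 1496 lower, where 1016 would be expected by chance; with scaling on the spike-in probes it gave 926. The other 2 splits of the 4 arrays gave 824 and 185, and 3 splits cannot give a share under 0.05. Separated groups in all 4 pairs were found for 47.0 percent of genes, where chance gives 33.3 percent. The count of called genes moved with the array left out: it was 44 without scytonemin 1, 40 without control 2, 2 without scytonemin 2 and 1 without control 1, and the count at an unadjusted p under 0.05 was 4641, 1313, 2158 and 1398.

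By size alone, 57 genes differed by at least 2-fold in every pair of a treated and a control array, 21 higher and 36 lower. Of these, 11 higher and 11 lower genes were above background on all arrays, and 14 higher and 22 lower genes had a symbol. The other 10 and 25 rest on signals not well above background on some array. In a count added after seeing the data, with such signals raised to the array's lowest signal well above background, 16 higher and 17 lower genes were still 2-fold in every pair. With normexp the counts were 5 higher and 3 lower scaled by the 75th percentile and 5 and 4 scaled by quantiles, and with no filter on dim probes 75 and 59. EGR1, MMP26, TFCP2L1, AMBP, CYP1A1 and CDKN1A were among the higher genes, and ANKRD1, TNNC1, CCN2 and ZBED2 among the lower ones. The other splits of the arrays gave 3 and 1 such genes, and in simulated data 23 of 20130 genes without a change were also 2-fold in every pair. Leaving out an array raised the counts, since fewer pairs must pass: to 34 higher and 85 lower without control 1, 126 and 126 without scytonemin 1, 46 and 117 without control 2, and 54 and 47 without scytonemin 2.

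Fixed gene lists were compared with all other genes to ask which processes moved. Immediate early genes, NRF2 targets, and NF-kB targets and inflammatory cytokines rose, and genes of the G2 and M phases of the cell cycle fell. In all, camera called 13 of 34 lists, 10 higher and 3 lower. Some lists share members, so the called lists are not separate evidence. HMOX1 and FTL are in both the NRF2 and the iron handling list. NQO1 is in the NRF2 and aryl hydrocarbon receptor lists, and SESN2 in the ATF4 and p53 lists. With an estimated correlation camera called 0 lists. Fry, which tests a list against no change and not against other genes, called the aryl hydrocarbon receptor list, by direction (adjusted p = 0.0486) and in either direction (0.0334). Its member NQO1 was on no control array well above background, and fry used the value without the bound.

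Immediate early genes and MAPK feedback regulators, the fast transcriptional response to growth factor and stress signals, rose: 25 of 26 measured members were higher and PHLDA1 (-0.13) was lower, with a median log2 fold change of 0.49 (camera adjusted p = 1.17e-12; adjusted p = 0.669 with an estimated correlation). Of these, 15 passed when adjusted over the list alone, and 0 passed over all genes. EGR2 was at least 1.96-fold higher, and EGR1 is given above. NRF2 targets, the antioxidant and detoxification programme, rose with 26 of 29 members higher and a median of 0.38 (camera adjusted p = 6.29e-10; adjusted p = 0.669 with an estimated correlation). Among them 10 passed when adjusted over the list alone, including the quinone reductase NQO1, at least 4.25-fold higher, and haem oxygenase HMOX1 (1.14 ± 0.16). NF-kB targets and inflammatory cytokines rose with 17 of 21 members higher and a median of 0.39 (camera adjusted p = 1.13e-06, and 0.669 with an estimated correlation). Against the control mean the median was 0.22 in scytonemin 1 and 0.52 in scytonemin 2. Adjusted over the list alone, 9 members were higher and 1, the chemokine CCL2 (-0.80 ± 0.11), was lower. The neutrophil chemoattractant CXCL8 (2.69 ± 0.42) and the chemokine CCL20 (1.74 ± 0.46) were each well above background on 1 of 2 control arrays, so these values are approximate; CCL20 was at 1.09 without scytonemin 2 and 2.38 without scytonemin 1.

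The G2 and M phase list, genes of mitotic entry and chromosome segregation, fell with 39 of 40 members lower and a median of -0.20 (camera adjusted p = 3.76e-08; adjusted p = 0.669 with an estimated correlation). No member passed when adjusted over the list alone; the largest changes were in the cytokinesis protein ANLN (-0.58 ± 0.16) and topoisomerase TOP2A (-0.48 ± 0.13), and CCNB2 was higher (0.28 ± 0.10). ATF4 and amino acid response genes rose with 26 of 31 members higher and a median of 0.18 (camera adjusted p = 7.37e-05, and 0.669 with an estimated correlation). The largest values were in SESN2 and the stress phosphatase subunit PPP1R15A (1.09 ± 0.29), but 0 members passed when adjusted over the list alone. Targets of p53 rose with 20 of 28 members higher and a median of 0.14 (camera adjusted p = 0.00191; adjusted p = 0.669 with an estimated correlation). Adjusted over the list alone, SESN2, CDKN1A and the stress cytokine GDF15 (0.93 ± 0.15) passed. Aryl hydrocarbon receptor targets rose with 8 of 10 members higher and a median of 0.20 (camera adjusted p = 0.00256; adjusted p = 0.669 with an estimated correlation), and NQO1 and CYP1A1 passed when adjusted over the list alone.

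Interferon response genes rose with 16 of 24 members higher and a median of 0.15 (camera adjusted p = 0.0121), OASL (0.71 ± 0.27) and IFI44 (0.67 ± 0.24) being the largest. The cholesterol synthesis list was called higher by camera (adjusted p = 0.0121) with 22 of 24 members higher and a median of 0.18, but 3 members were higher in all 4 pairs and 0 passed when adjusted over the list alone. Its largest values were in MVD (0.44 ± 0.33) and CYP51A1 (0.43 ± 0.17). Mesenchymal and motility genes rose with 11 of 16 members higher and a median of 0.18 (camera adjusted p = 0.0299), although the 2 largest changes went opposite ways: the matrix protein SPARC (0.91 ± 0.33) and ZEB1, a repressor of epithelial genes (-0.70 ± 0.25). Iron handling genes rose with 10 of 12 members higher and a median of 0.13 (camera adjusted p = 0.0355), HMOX1 passing when adjusted over the list alone and the ferritin light chain FTL at 0.51 ± 0.12. Glycolysis genes fell with 14 of 21 members lower and a median of -0.15 (camera adjusted p = 0.0248). The glucose transporter SLC2A3 (-0.84 ± 0.11) passed when adjusted over the list alone and PGAM1 was at -0.29 ± 0.09. Heat shock genes fell with 15 of 17 members lower and a median of -0.14 (camera adjusted p = 0.0298), CRYAB (-0.32 ± 0.08) and HSPH1 (-0.32 ± 0.11) being the largest. With an estimated correlation the adjusted p was 0.825 for cholesterol synthesis and 0.669 for the other 5 of these lists.

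Leaving out 1 array ended the call of each of those 6 lists. The adjusted p of cholesterol synthesis was 0.433 without control 1 and 0.650 without scytonemin 2, and that of the interferon list was 0.553 without scytonemin 1 and 0.0537 without control 2. Glycolysis had 0.0942 without control 1, 0.134 without scytonemin 1 and 0.0508 without control 2. Heat shock had 0.177 without control 2 and 0.114 without scytonemin 2, mesenchymal genes 0.0695 and 0.0581 without the same arrays, and iron handling 0.133 without scytonemin 1. Over the 4 fits the range was 3.34e-05 to 0.650 for cholesterol synthesis, 2.51e-05 to 0.553 for interferon, 0.0140 to 0.134 for glycolysis, 0.0232 to 0.177 for heat shock, 0.0374 to 0.0695 for mesenchymal genes and 0.0145 to 0.133 for iron handling.

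**Figure D2:**
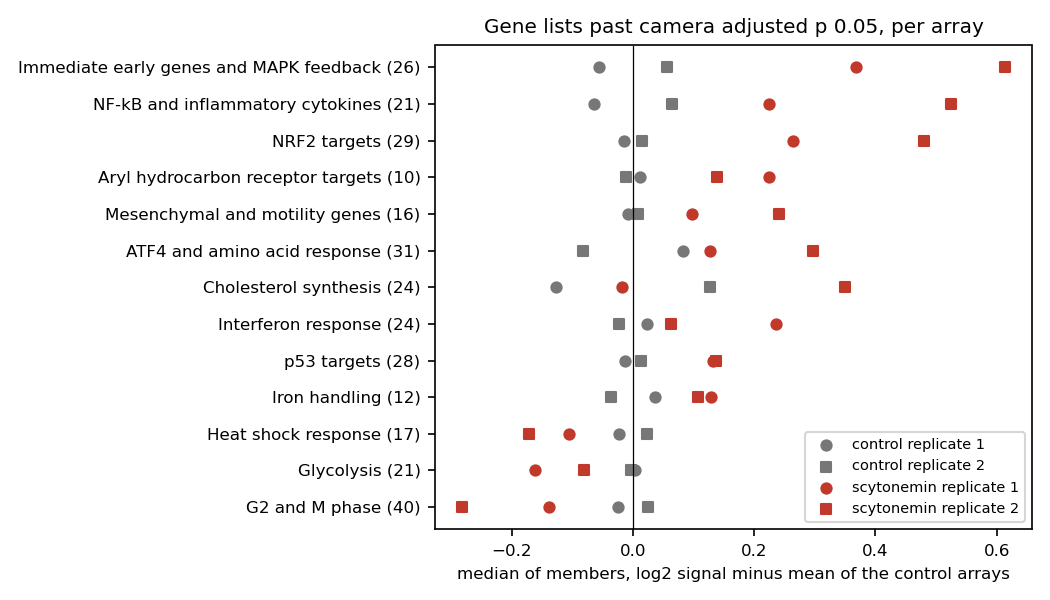
Median over the members of each called gene list of the log2 signal minus the mean of the 2 control arrays (x axis), per array, with the number of measured members in brackets; grey marks are control replicates and red marks scytonemin replicates. The immediate early list lies at 0.37 and 0.61 in the treated arrays and at -0.06 and 0.06 in the controls, while for cholesterol synthesis scytonemin 1 (-0.02) lies between the controls.

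The other 21 lists did not pass camera. Nearest were apoptosis regulators (18 of 28 higher, adjusted p = 0.0612; BMF and CASP10, 0.45 ± 0.09), oxidative phosphorylation (27 of 35 lower, 0.0628; NDUFB5, -0.43 ± 0.23) and G1 to S and DNA replication (35 of 44 lower, 0.0811; GINS1, -0.25 ± 0.11). The adjusted p was 0.109 for metallothioneins and zinc (11 of 13 lower; SLC39A10, -0.36 ± 0.11, and SLC30A1, 0.49 ± 0.11), 0.132 for the unfolded protein response (16 of 22 lower; CALR, -0.33 ± 0.12), 0.132 for autophagy and lysosome (25 of 38 higher; WIPI1, 0.61 ± 0.16, and SQSTM1, 0.58 ± 0.18), and 0.137 for DNA repair by recombination (15 of 20 lower). It was 0.188 for peroxisome proliferator and fat oxidation (8 of 11 higher; ACADVL, 0.40 ± 0.10) and 0.249 for canonical histone genes (14 of 18 higher). It was 0.377 for WNT targets (7 of 11 higher; NKD1, 0.53 ± 0.13), 0.487 for epithelial markers (11 of 19 lower), and 0.752 for the oestrogen and progesterone response (9 of 18 higher). It was 0.793 for cyclin and CDK regulators of G1 (13 of 20 lower; CDK6, -0.34 ± 0.10), and 0.999 for hypoxia (11 of 20 lower), fatty acid synthesis (9 of 15 lower), and ribosome biogenesis and MYC (16 of 27 lower; MYC, 0.34 ± 0.10). Single members of these lists passed when adjusted over the list alone: E-cadherin CDH1 (-0.65 ± 0.08), the cytokine LIF (0.81 ± 0.11) and PDZK1 (-0.62 ± 0.11) of the oestrogen list, BAMBI (-0.49 ± 0.09) of the WNT list, BMF, CDKN1A, and DDIT4 (0.97 ± 0.16) and adrenomedullin ADM (-0.92 ± 0.12) of the hypoxia list. Median, mean and test differed in sign for hypoxia, fatty acid synthesis, ribosome biogenesis and MYC, and G1 regulators.

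Markers of other cell types were compared between the groups. The test asks whether these markers differed and cannot show whether such cells were present in both groups. Camera gave an adjusted p of 0.383 for endothelial markers (4 of 5 higher; ESAM, 0.39 ± 0.23, and CLDN5, -0.76 ± 0.31), 0.531 for squamous keratinocyte markers (5 of 7 higher; SPRR3, 0.18 ± 0.09, and SPRR1B, -0.39 ± 0.31), 0.664 for stromal fibroblast markers (3 of 5 higher; FBLN1, -0.53 ± 0.11, which passed when adjusted over the list alone while its other probe was at -0.03) and 0.999 for leukocyte markers (5 of 10 higher; CD68, 0.56 ± 0.21). The median and the test differed in sign for stromal markers, at 0.01 and a mean of -0.08, and for leukocyte markers, at -0.03 and a mean of 0.02.

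The authors' deposited tables of higher and lower genes were set against these values; they were chosen on these samples and are not independent evidence. Of 41 entries with a ratio from 2.01 to 7 in the authors' deposited table of higher genes, 37 were matched. Of these, 25 were matched by accession and 12 by symbol, where the probe may differ from the authors'. The entry named p21 (ratio 2.87) was not matched, although CDKN1A, which encodes p21, was 2.54-fold higher here. All 37 were higher here, 22 by at least 2-fold and 7 by 2-fold in every pair. Of 26 entries with a ratio from 0.18 to 0.58 in the authors' deposited table of lower genes, 25 could be matched, 23 by accession and 2 by symbol, of which 22 were lower here, 18 by at least 2-fold and 8 by 2-fold in every pair. Of the authors' lower entries, 3 had a deposited ratio short of 2-fold. Over both directions 60 entries had a value here, with a median absolute log2 difference of 0.06 from the authors' ratio. Among these, 5 differed by over 1.5 times. By limma 0 of the matched genes passed the adjusted p threshold, while 34 higher and 18 lower entries had an unadjusted p under 0.05. The authors' deposited table gave its highest ratios to EGR1 (7), KIF6 (3.7), MMP26 (3.46), CABP1 (3.45) and SESN2 (3.03). KIF6 (1.82 ± 1.26 here) was higher in 3 of 4 pairs and rested on scytonemin 2, without which its log2 fold change was -0.08. The authors' deposited table gave its lowest ratios to PAAF1 (0.18), THAP5 (0.21), TTC15 (0.35), TNNC1 (0.36) and EDN2 (0.38). PAAF1 and THAP5 were not tested here because 1 spot of each had an outlier mark, and TTC15, now TRAPPC12, could be matched by symbol to another probe alone (0.19 ± 0.10). The count of higher entries at 2-fold or more was 11 without scytonemin 2 and 30 without scytonemin 1.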

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

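The tests of the explanations in this part were chosen after the results were seen; the alternatives they draw on were planned, except array position and spike-in scaling, and except the marked spots of PAAF1 and THAP5. The spike-in probes, which report synthetic RNA added to each sample and were not used in the comparison, lay 0.331 above the control mean in scytonemin 2 (log2 signal relative to the array's 75th percentile, 7 probes), against -0.13 in scytonemin 1 and -0.07 and 0.07 in the controls; this signal stood above both control samples.

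Immediate early genes, NRF2 targets and NF-kB targets were higher with scytonemin on both treated arrays. A steady trend with array position on the slide would put scytonemin 1 between the 2 controls. Against the control mean, the 3 list medians were 0.37, 0.26 and 0.22 in scytonemin 1. In control 2, the higher control, they were 0.06, 0.02 and 0.06, which argues against such a trend as the whole cause. With position as a covariate the largest camera adjusted p of the 3 lists was 6.1e-08. That value cannot decide, since it rests on the preset correlation, while 0.43, 0.29 and 0.34 were estimated. An effect of scytonemin 2 alone is argued against too, since without that array it was 2.51e-05. The alternatives for scaling, background correction, dim probes or outlying spots gave a camera adjusted p of at most 0.000974. Over the 13 processing alternatives the camera adjusted p of these lists ranged from 1.73e-29 to 0.000974 with the preset correlation. In the main fit it was 0.669 for each with an estimated correlation and 0.207 for each by fry, where the calls were lost. Handling or vehicle differences between the groups, and an effect of scytonemin itself, stay open and were not tested.

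PAAF1 and THAP5 had the lowest ratios in the authors' deposited table of lower genes, and each had a spot with an outlier mark. A non-uniform spot may account for both: with all arrays the log2 difference was -2.51 for PAAF1, and without scytonemin 2, whose spot was marked, it was 0.0259. For THAP5 it was -2.30, and without control 1, whose spot was marked, it was -0.159. PAAF1 had a processed signal of 92.9 on the marked spot and 3644 to 4578 on the other arrays, and THAP5 had 3684 on the marked spot and 121 to 161 on the others. No biological explanation was tested for these spots.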

How the results depend on the processing

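Array position as a covariate and scaling on the spike-in probes were chosen after seeing the data; the other alternatives were planned. In a fit without 1 array, the lone sample of its group is assumed to vary like the other group. A slide or scan block could not be run. Of 13 called lists, 7 (immediate early, NRF2, G2 and M phase, NF-kB, ATF4, p53 and aryl hydrocarbon receptor) stayed past the threshold with the same direction in all 13 processing and 4 leave-out alternatives with the preset correlation. All 7 lost the call with an estimated correlation (adjusted p = 0.669 each), and all but the aryl hydrocarbon receptor list (0.0486) lost it by fry (0.207 to 0.453). Of 81 named genes, 72 kept their sign in every alternative that measured them, and PLK1 ranged from -0.37 to -0.14. A gene with the same sign in every pair, such as PLK1, cannot change sign when 1 array is left out. For such genes the leave-out part of this count was fixed in advance. Of the 21 other lists, 7 passed in some alternative with the preset correlation. They were oxidative phosphorylation, apoptosis regulators, the unfolded protein response, G1 to S and DNA replication, metallothioneins and zinc, DNA repair, and histone genes. Over the processing alternatives the camera adjusted p of oxidative phosphorylation ranged from 0.000764 to 0.527, and that of apoptosis regulators from 0.0112 to 0.221. Signal over background limits genes such as CXCL8, NQO1 and EGR2, whose signal was not well above background on 1 or both control arrays. Except where a cause is given, the cause was not tested.

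The number of genes changed by scytonemin was 1. It was 4 at an adjusted p threshold of 0.1, 4 with quantile normalization, 0 with normexp and the 75th percentile, 9 with normexp and quantile normalization, 0 with no filter on dim probes, 0 with probes well above background on all arrays, 69 with an intensity trend and robust prior, 5 with the mean of a gene's probes, 2 with all probes tested and 2 with array position as a covariate. Beside those counts of 0, limma gave 2292, 2013 and 2537 genes at an unadjusted p under 0.05. The called transcript was on no control array above background, so the stricter filter removes it by construction. Without 1 array the count ranged from 1 (without control replicate 1) to 44 (without scytonemin replicate 1). Scaling on the spike-in probes gave 215, and 926 at an unadjusted p under 0.05, fewer than the 1016 expected by chance. It shifted the median of all genes to a log2 fold change of -0.11. With it the prior degrees of freedom were infinite, so that all genes took 1 variance. This scaling differs from the main one only by a constant per array. These changes therefore come from a shift shared by all genes of an array, and what caused that shift was not tested. A replicate block, in which samples are paired by replicate number, gave 11; the pairing is not established (deviations of the same replicate number correlated at 0.146 over genes).

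Genes 2-fold higher in every pair (21) numbered 5 with normexp and the 75th percentile, 5 with normexp and quantile normalization, 75 with no filter on dim probes and 11 with probes well above background on all arrays; genes 2-fold lower (36) numbered 3, 4, 59 and 11. The offset of normexp shrinks folds of dim genes by construction. Without 1 array, where fewer pairs must pass, the higher genes ranged from 34 to 126 and the lower genes from 47 to 126. Of the authors' higher genes, 22 were at least 2-fold higher, 12 with normexp and quantile normalization and 11 to 30 without 1 array. Camera called 13 lists, 0 with an estimated correlation, and fry called 1.

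Of the called lists, the adjusted p of iron handling was 0.0594 with normexp and the 75th percentile and 0.439 with no filter (range over processing 0.000103 to 0.439). That of the interferon list was 0.0619 with all probes tested (1.29e-05 to 0.0619), and that of cholesterol synthesis 0.290 with array position as a covariate (0.000112 to 0.290). With scaling on the spike-in probes it was 0.281 for heat shock (0.000693 to 0.281), 0.270 for glycolysis (0.000321 to 0.270) and 0.0872 for mesenchymal genes (0.0125 to 0.0872). The median of cholesterol synthesis ranged from -0.018 without scytonemin replicate 2 to 0.35 without scytonemin replicate 1.

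Lists that were not called changed direction, with these adjusted p. Fatty acid synthesis did so with the 75th percentile over probes above background on all arrays (0.993), array position (0.254), fry (0.978), no filter (0.758), normexp and the 75th percentile (0.776), probes above background on all arrays (0.947) and quantile normalization (0.985). Ribosome biogenesis and MYC did so with fry (0.978), the mean of a gene's probes (0.997), no filter (0.578), normexp and quantile normalization (0.777), normexp and the 75th percentile (0.331), probes above background on all arrays (0.947), quantile normalization (0.779) and the replicate block (0.961). The hypoxia response did so with all probes tested (0.984), array position (0.844) and spike-in scaling (0.770), leukocyte markers (0.548) and squamous keratinocyte markers (0.871) with array position, and G1 regulators with spike-in scaling (0.747). Without 1 array, the adjusted p of lists that changed direction in at least 1 such fit ranged from 0.0400 to 0.828 for histone genes, 0.541 to 0.990 for G1 regulators, 0.0124 to 0.779 for DNA repair, 0.184 to 0.990 for epithelial markers, 0.365 to 0.541 for fatty acid synthesis, 0.579 to 0.999 for the hypoxia response, 0.139 to 0.957 for leukocyte markers, 0.432 to 0.798 for the oestrogen and progesterone response, 0.531 to 0.689 for ribosome biogenesis and MYC, 0.273 to 0.899 for squamous keratinocyte markers, 0.0899 to 0.759 for stromal fibroblast markers, 0.558 to 0.990 for TGF-beta targets and 0.00323 to 0.957 for the unfolded protein response.

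Of the named genes, 9 changed sign. HBA2 was at 0.12 and ME1 at 0.094 with normexp and the 75th percentile, and COL6A3 at -0.10 with array position. Without 1 array, the log2 fold change ranged from -0.014 to 0.59 for ACSS2, -0.82 to 0.10 for CCNE2, -0.14 to 0.49 for COL6A3, -1.32 to 0.093 for ESRP1, -0.076 to 3.72 for KIF6, -0.41 to 0.0073 for RAD51AP1 and -0.18 to 1.55 for XRCC2.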

Other observations

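In this part the target lists below were added after ANKRD1, CCN2 and CCN1 had been seen to be lower, with their other members not yet seen, and the genes named next were chosen after their values were seen. TGF-beta targets moved both ways: the camera adjusted p was 0.909, the median was 0.04 and the mean -0.08. Adjusted over the list alone, 4 members were higher, ID4 (0.66 ± 0.18) and ID1 (0.51 ± 0.09) among them, and 5 were lower, CCN2 (-1.38 ± 0.17) and CCN1 (-0.82 ± 0.19) among them. Lower signals were also measured for caveolin CAV1 (-1.31 ± 0.12), caldesmon CALD1 (-1.19 ± 0.10), and endothelin EDN1 (-1.12 ± 0.08), with an adjusted p of 0.128 each. The cytokine IL6 was higher (0.95 ± 0.08, adjusted p = 0.128).

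ANKRD1, CCN2 and CCN1 are known targets of the YAP and TEAD transcription factors, and lower activity of these may account for their lower signals. In a list of 19 other measured targets, 13 were lower, with a median of -0.217 and a spread of 0.105 (camera adjusted p = 0.0306 over the 2 added lists; adjusted p = 0.393 with an estimated correlation, and 0.133 by fry). FSTL1 (-0.62 ± 0.10) was the 1 member past the threshold adjusted over the list alone. Without scytonemin 2 the median was -0.0776 and the adjusted p 0.208, against 0.00597 to 0.0475 without each of the other arrays. A list of 18 targets of SRF and MRTF, another pair of regulators of these genes, had a median of -0.0780 with a spread of 0.0189, so that it lay below 0, but 10 were lower and the camera adjusted p was 0.311, so the prediction was met in part and the test leaves this explanation open. By fry for change in either direction the adjusted p was 0.0124 for each of the lists.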
